A study of Homo sapiens with 2 samples.

How the data were processed

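The series mapped 5-methylcytosine in genomic DNA of HEK293T, a transformed human embryonic kidney cell line, by TAD-seq and by bisulfite sequencing (BS-seq), with 1 library per method. In TAD-seq, per the labels' protocols, a TET enzyme first oxidises 5-methylcytosine and a cytosine deaminase then converts the unprotected cytosines, so that a methylated cytosine is read as C and an unmethylated cytosine as T, without bisulfite. Lambda phage DNA and a methylated control duplex were added to the TAD-seq material, and the deaminated DNA went through a pair of PCR amplifications before sequencing. The spike-in reads were not analysed here, and details of the BS-seq protocol beyond the method's name were not used here.

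Per the submitters' processing notes, the reads were handled with FastQC 0.11.8, cutadapt 3.5, Trimmomatic 0.39, Bismark 0.24.0 and SAMtools 1.9 on the genome build GRCh38.p13. Their parameters, the removal of PCR duplicates and the rule for calling a cytosine methylated are not given in the sources used here. The authors deposited 1 list of cytosines per library, with the read counts that call the cytosine methylated and unmethylated on its own strand, as raw counts. The deposited level is a fraction, and it equalled methylated over all reads within 5e-07 at every cytosine. The deposited p-value and its adjusted p-value belong to each cytosine. In 2000 sampled cytosines per context and library, the p-value equalled an upper binomial tail at 1 fixed error rate. That rate was 0.177% at CpG, 0.969% at CHG and 0.155% at CHH in TAD-seq, where H stands for A, C or T. It was 0.300%, 0.306% and 0.305% in BS-seq.

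Tested on the values, each list holds only cytosines with at least 5 reads, a level of at least 5.0% and an adjusted p-value under 0.01. A cytosine absent from a list was therefore either uncovered or not called, and these cases cannot be separated. All levels here are levels of listed cytosines and lie above the level of the whole genome, and the sites unmethylated in one library were not compared. The error rates also set how many methylated reads a call needs. A CpG cytosine could be listed with 1 methylated read in TAD-seq, as 262490 were, while BS-seq needed at least 2. Intervals are Wilson intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. There were no replicates, so no difference between the methods has a replicate check. Every test on reads compares these 2 libraries, not the methods or conditions.

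Analyses used chromosomes 1 to 22, X and Y for counts of cytosines, and chromosomes 1 to 22 and X for genes. Unplaced scaffolds were kept apart, except in the totals, depths and single-cytosine levels of each whole list. Reads of a CpG site's strands were added where both libraries listed the strand. Sites with at least 10 reads in both libraries were compared by Pearson's r, Spearman's rho and a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and differed at an adjusted p under 0.05 and a difference of at least 25 percentage points. Bins of 100 kb needed 100 cytosines listed in both. An interval for r came from 1000 bootstrap draws of the 23 chromosomes. CpG density is the number of CpG sites in either list within 100 bp of a cytosine. Some levels were taken only where the opposite strand of the same CpG, called the partner strand, had a given level, so that a cytosine was not chosen by its own reads.

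Genes came from a RefSeq gene table of GRCh38.p14, whose primary chromosomes have the coordinates of the build used for the files. As a check of the coordinates, listed CpG cytosines averaged 6.79 per 500 bp at protein-coding gene ends in TAD-seq and 9.47 at 1000 bp outside them. The table gives no strand and no sequence was used here, so several measures were adapted after the data were seen. Both gene ends, from 1000 bp outside to 500 bp inside, stand in for promoters. Gene bodies from end to end stand in for other gene regions and for list levels, listed CpG density stands in for GC content, and exons, UTRs, CpG islands and flanking bases were not analysed here. A gene body or gene end needed 10 listed cytosines and 100 reads in each library. It differed at an adjusted p under 0.05 and at least 10 percentage points, by a two-sided Fisher's exact test on summed reads. Reads of neighbouring sites share fragments, so these p-values are too small and the size threshold carries the call.

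The groups, the thresholds for sites and gene ends, the 17 gene lists, the naming rule and part of the alternative settings were fixed before the data were examined. The settings added later are named with their effects. The lists were 12 sets of named genes and 5 families chosen by symbol. Each list's median was placed among 10000 random protein-coding lists of the same size, matched by decile of listed CpG sites per kb of gene, as a description of these libraries. The rule named the 10 gene ends with the largest and the 10 with the most negative difference among those that differed, the members of each list with the highest and lowest mean level and the largest absolute difference, imprinted genes between 30% and 70% in both libraries, and the 3 largest and 3 most negative single sites. Some genes that these choices would name are not reported here. Other named genes are said to be chosen after their values were seen. Alternatives covered the read minimum, strands, autosomes, the deepest 0.1% of sites, thinning of the deeper library, bin and window sizes, thresholds and the matching of lists.

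The procedures were tested on simulated data at the real depths, with 1 level per site in both libraries and known changes added. The sites and gene ends to be lowered were drawn from highly methylated ones, and no general offset was simulated. Of 200 sites lowered by 70 points among 11679247 tested, 23.5% were recovered, of 200 lowered by 50 points 4.5%, and of 200 lowered by 30 points 0.5%. No unchanged site was called. Of 200 gene ends lowered by 15 points among 23235 tested, 65.5% were recovered, and of 200 lowered by 30 points 99.5%, with 21 unchanged ends called. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0, numba 0.67.0 and matplotlib 3.10.9.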

Results

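The data were 2 lists of methylated cytosines from HEK293T DNA, 1 from TAD-seq and 1 from BS-seq. With unplaced scaffolds included, TAD-seq listed 35295815 cytosines and BS-seq 33964562. CpG cytosines made up 34432178 of the TAD-seq list and 33684508 of the BS-seq list, with 397659037 and 321422132 reads over them. The median depth was 10 reads per listed CpG cytosine in TAD-seq and 9 in BS-seq, and 95% of listed CpG cytosines had at most 23 and 17 reads. The coefficient of variation of depth was 2.07 in TAD-seq and 1.61 in BS-seq. At least 10 reads covered 18383405 CpG cytosines in TAD-seq and 13582928 in BS-seq.

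The first comparison asked whether the bisulfite-free method gave the same map as BS-seq. On the chromosomes, 27631557 CpG cytosines were in both lists, which is 80.4% of the TAD-seq list and 82.1% of the BS-seq list. The share of TAD-seq cytosines also listed by BS-seq was 66.1% at 5 reads and 88.8% at 20 reads, and 82.8% where the level was at least 80% against 48.1% where it was below 20%. TAD-seq alone listed 6754300 CpG cytosines, with a level of 61.7% and a median of 8 reads. BS-seq alone listed 6009196, with a level of 70.7% and a median of 7 reads.

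The methylation level over all listed CpG cytosines of the chromosomes was 71.8% in TAD-seq and 78.3% in BS-seq, a difference of -6.48 percentage points. The counting intervals round to these same levels and do not bound differences between preparations. Over cytosines in both lists the levels were 73.8% and 79.7%. TAD-seq was lower on every autosome, by differences from -7.69 to -5.40 points with an SD of 0.444 over the 22 autosomes. Chromosome 16 had the most negative difference, and without the deepest 0.1% of sites the difference there was -6.02. Chromosome 17 had the highest level in both libraries, 78.6% and 84.6%, and chromosome X the lowest, 63.2% and 68.9%. Cytosines inside protein-coding genes had levels of 77.9% and 83.7%, and those outside every annotated gene had 69.0% and 74.8%. The excess inside genes was 8.93 points in TAD-seq and 8.91 in BS-seq. The median level of a single listed CpG cytosine was 80% in TAD-seq and 87.5% in BS-seq, and 22% against 37.1% had no unmethylated read.

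Across 11679247 CpG sites with at least 10 reads in both libraries, Pearson's r was 0.825 (0.813 to 0.838 over draws of chromosomes) and Spearman's rho 0.683. Sites are not independent replicates. The mean difference was -5.29 points with an SD of 12.6, and 93.1% of sites lay within 25 points. At 1351480 CpG sites where both strands had at least 10 reads in both libraries, r between strands was 0.759 within TAD-seq and 0.825 within BS-seq. Between the libraries r was 0.794 on the plus strand and 0.793 on the minus strand, so it lay between the values that strands of single libraries gave. Across 27921 bins of 100 kb, r was 0.996 (0.996 to 0.997) and rho 0.996. TAD-seq was lower in 27891 bins and higher in 30. The bins ranged from 19.1% to 94.2% in BS-seq. Of the bins, 1389 lay below 50% in BS-seq and 3363 in TAD-seq, and 1388 in both. The most negative bin, on chromosome 1 from 600000 to 699999, had 44.3% in TAD-seq and 61.2% in BS-seq. The bin with the largest positive difference, on chromosome 10 from 108700000 to 108799999, had 48.5% and 44.2%.

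**Figure D1:**
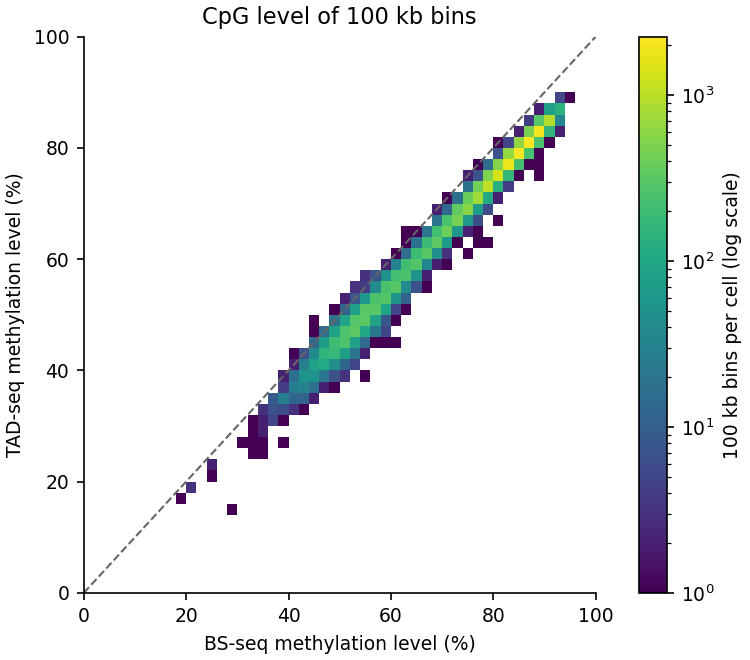
Methylation level of 27921 bins of 100 kb in BS-seq (horizontal, %) and TAD-seq (vertical, %), with colour for the number of bins per cell on a log scale and a dashed line of equal levels. Nearly all bins lie below the line, 27891 of them, with r of 0.996.

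Of the CpG sites tested, 149 passed the adjusted threshold, all of them lower in TAD-seq, and 17 of these differed by at least 25 points. No site was higher in TAD-seq by this test. Of the 17 sites, 9 lay between 8219669 and 8219707 on chromosome 21, nearest to RNA45SN2, a gene of the repeated ribosomal RNA units, a group named after its values were seen. The 3 most negative sites were elsewhere. At position 140804252 of chromosome 7, inside BRAF, TAD-seq had 3 methylated of 23 reads and BS-seq 17 of 17. At position 90072971 of chromosome 3, outside every annotated gene, the counts were 10 of 43 and 17 of 17. At position 62792929 of chromosome 14, inside KCNH5, a potassium channel gene, they were 6 of 35 and 17 of 19. With BS-seq methylated reads thinned by the overall ratio of levels, a setting added after seeing the data, 1 site differed, and with TAD-seq thinned to the BS-seq total 8. Without the deepest 0.1% of sites, 0 sites differed. The 3 most negative sites were among the 6 of the 17 still tested there, with the same reads, and the smallest adjusted p of the 6 was 0.150, so their calls ended through the adjustment. At an unadjusted p under 0.05, 428269 sites were lower and 53378 higher in TAD-seq. In simulated reads at these depths, 23.5% of sites lowered by 70 points and 0.5% of sites lowered by 30 points were recovered. Only highly methylated sites were lowered and no general offset was simulated, so these rates need not hold for the real comparison.

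Over 18740 protein-coding gene bodies the median level was 81.1% in TAD-seq and 86.9% in BS-seq, the median difference was -5.76 points, and r across genes was 0.979. TAD-seq was lower in 18524 bodies. A body differed in 481 cases by Fisher's exact test and the 10-point threshold, and 480 of these were lower in TAD-seq. The exception was APOA2, an apolipoprotein gene named after its value was seen, with 85.5% in TAD-seq and 72.8% in BS-seq. Taken from the median gene, a setting added after seeing the data, 66 bodies differed, with the adjusted test still against equal levels.

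Gene ends showed a wider spread. Of 23235 gene ends, which belong to 16073 genes, 2914 differed by Fisher's exact test with Benjamini-Hochberg adjustment, 2901 lower and 13 higher in TAD-seq. Genes can share an end, and 264 of the tested ends and 31 of those that differed repeat the reads of another. The median difference was -5.69 points and 90.3% of ends were lower in TAD-seq. Most of these calls carry the general offset. Taken from the median gene end, 541 of the ends that passed the adjusted test were at least 10 points below it and 16 at least 10 above. That test was still against equal levels, and 6145 lower but only 16 higher ends passed it. These counts therefore do not compare the sides. Ends that differed had a median level of 72.8% in TAD-seq and 85.9% in BS-seq. The rank correlation of the difference with the number of listed CpG sites was -0.0606.

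The 10 most negative gene ends were at KCNJ12, DIPK1B, LOC124903151, PHB1, MTA3, TMEM164, ZNF829, CD70, HOXC11 and UBQLN2. KCNJ12, an inward rectifier potassium channel gene on chromosome 17, had 41.5% (36.9 to 46.2) in TAD-seq and 77.3% (70.3 to 83.1) in BS-seq at its lower-coordinate end, over 25 cytosines between 21375488 and 21376455. The lower-coordinate end of HOXC11, a homeobox gene on chromosome 12, had 41.2% (36.8 to 45.7) and 69.8% (64.3 to 74.9) over 37 cytosines. PHB1, the prohibitin gene, had 62.2% and 92.2% at its higher-coordinate end. MTA3, a subunit gene of a chromatin remodelling complex, had 32% and 61.6% at its lower-coordinate end. CD70, a TNF family ligand gene, had 54.7% and 83.9%. On chromosome X, TMEM164 had 38.2% and 67.6%, and UBQLN2, a ubiquilin gene, 15% and 43.4%. The differences of these 10 ends ran from -35.8 to -28.3 points.

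Among the 13 ends that were higher in TAD-seq, the 10 largest differences were at LDOC1, TBPL1, ADNP, BMP8B, ERVV-1, SFTPB, ARHGAP10, IGFBPL1, LAMB3 and CENPF, from 18.9 to 11.7 points. In simulated reads at these depths, 21 unchanged ends were called, counted in both directions and with equal levels in the libraries. The simulation had no general offset, so it does not give the number of false calls among these 13, and false calls among them are not excluded. LDOC1 on chromosome X had 53.5% (46.3 to 60.6) in TAD-seq and 34.7% (29.0 to 40.7) in BS-seq over 32 cytosines between 141176721 and 141178051. SFTPB, a surfactant protein gene, had 87.2% and 73.3%, and LAMB3, a laminin subunit gene, 52.3% and 39.5%.

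Olfactory receptor genes were the least methylated list, with medians of 56.9% in TAD-seq and 62.9% in BS-seq over 186 measured bodies of 390. These medians lay below all matched random lists in both libraries. OR12D3 was highest, at 87.9% and 90.7%, and OR2A2 lowest, at 20.9% and 23.3%. OR13G1 had the largest difference, 59.1% against 77.0%. The 53 clustered protocadherins, neuronal adhesion genes in tandem arrays, had medians of 62.9% and 70.6%, again below all matched lists. Annotated bodies of such arrays can overlap, and shared reads were counted for each gene. The 53 are therefore not independent members, and their percentile and count of bodies that differ do not allow for this. Their range ran from PCDHB10, at 48.1% and 49.3%, to PCDHGC4, at 75.3% and 83.4%, and PCDHB16 had the largest difference of -11.6 points. Cytoplasmic ribosomal protein genes had 71.6% and 78.1% over 81 bodies, from RPL39 at 32.3% and 33.8% to RPL39L at 87.3% and 92.0%. RPL11 differed most, with 59.1% and 80.9%. The family rule by symbol also took in RPS19BP1 and RPL36A-HNRNPH2, named for this reason alone. Zinc finger genes of chromosome 19 had 77.8% and 83.9% over 249 bodies, from ZNF347 at 40.2% and 42.9% to ZNF561 at 89.6% and 95.6%. ZNF579 differed most, at 77.9% and 95.7%. Histone genes had 82.5% and 88.4% over 33 measured bodies of 87, from H3C7 at 27.2% and 39.7% to H3C11 at 94.7% and 96.5%. The other histone genes lacked the listed cytosines or reads that a body needed, so these medians do not describe the whole family. The median difference of olfactory receptors, -4.96 points, was the least negative of the 17 lists. By the adjusted test over all genes, 24 olfactory receptor, 6 protocadherin, 3 ribosomal protein, 10 zinc finger and 5 histone gene bodies differed. The counts adjusted over the list alone were 20, 6, 3, 10 and 5.

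**Figure D2:**
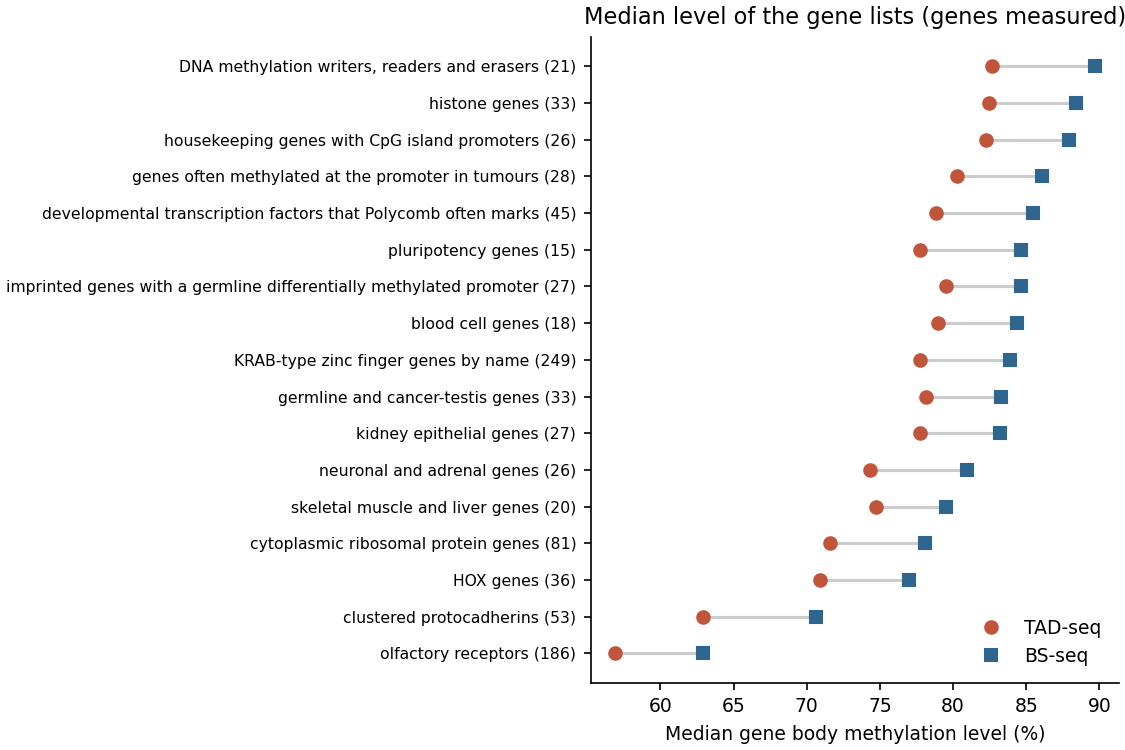
Median gene body methylation level (%) of the 17 gene lists in TAD-seq (circles) and BS-seq (squares), with the number of genes measured in brackets. TAD-seq lies below BS-seq in all 17 lists, and olfactory receptors are lowest in both, at 56.9% and 62.9%.

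The 36 measured HOX genes, which pattern the body axis, had median levels of 70.9% and 77.0%, below all matched random lists in both libraries. Their bodies ranged from HOXA9, at 22.7% (20.8 to 24.7) in TAD-seq and 33.4% (30.5 to 36.4) in BS-seq, to HOXD12, at 90.6% and 95.3%. HOXA7 differed most, at 48.2% and 65.4%. Of the 52 HOX gene ends tested, 12 differed, all lower in TAD-seq, and 14 when adjusted over the list alone. Among all tested gene ends 12.5% differed, nearly all lower in TAD-seq. Developmental transcription factors that Polycomb often marks had 78.9% and 85.5% over 45 bodies. HAND1 was lowest, at 47.4% and 54.2%, HAND2 highest, at 89.6% and 95.8%, and FOXF1 differed most, at 51.7% and 71.6%. Of their 73 gene ends, 10 differed, 9 of them lower in TAD-seq, and 11 when adjusted over the list alone. The exception was the higher-coordinate end of HAND1, named after its value was seen, with 49.6% in TAD-seq and 38.2% in BS-seq.

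Imprinted genes with a germline differentially methylated promoter had medians of 79.5% and 84.6% over 27 bodies. Intermediate bodies in both libraries were those of HYMAI (50% and 45.1%), MKRN3 (59.5% and 66.2%), SNRPN (58.9% and 63.5%), ZNF597 (62.1% and 69.9%), ZIM2 (56.3% and 61.0%) and PEG3 (58.8% and 64.5%). The measured span of PEG3 lies within that of ZIM2, so the bodies of these genes share reads. At gene ends, ZNF597 had 47.0% and 51.6% at its higher-coordinate end, PLAGL1 53.4% and 55.4% at its lower-coordinate end, and NAA60 41.8% and 53.2% at its lower-coordinate end. NNAT was highest, at 87.3% and 98.7%, and the only body of the list that differed. Of 28 gene ends of this list, 4 differed, and 5 when adjusted over the list alone.

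Genes often methylated at the promoter in tumours had medians of 80.3% and 86.1% over 28 bodies, from MGMT, a DNA repair gene, at 53.6% and 58.4% to CCND2 at 87.3% and 93.2%. TFPI2 differed most, at 64.6% and 80%. Of the 40 gene ends of this list, 4 differed, with the same count adjusted over the list alone. Among them were ends of ESR1, TFPI2 and CDH1, named after their values were seen. The higher-coordinate end of CDH1, the E-cadherin gene, had 78.1% in TAD-seq and 89.1% in BS-seq over 37 listed cytosines. Without strands, these ends cannot be assigned to promoters, so their levels are not promoter levels. Writers, readers and erasers of DNA methylation had 82.7% and 89.7% over 21 bodies, the highest medians of any list in both libraries. DNMT1, the maintenance methyltransferase gene, was highest, at 88.1% and 92.6%, and ZBTB33 on chromosome X lowest and most different, at 55.1% and 69.8%. Bodies that differed numbered 2 in this list, 1 among the tumour genes, 6 among HOX genes and 2 among the Polycomb-marked factors, with the same counts adjusted over the list alone.

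Lists of cell identity genes lay closer together. Kidney epithelial genes had medians of 77.7% and 83.2% over 27 bodies, from PKHD1 at 44.1% and 48.9% to SLC5A2 at 84.0% and 90.3%, and CALB1 had the largest difference of -7.81 points. Neuronal and adrenal genes had 74.3% and 80.9% over 26 bodies, from DCX at 43.2% and 48.8% to PNMT at 88.9% and 90.0%, and TH had the largest difference of -8.46 points. Skeletal muscle and liver genes had 74.7% and 79.5% over 20 bodies, from APOB at 53.2% and 58.2% to ACTA1 at 85.9% and 91.3%, and MYOD1 had 61.1% and 77.0%. Blood cell genes had 78.9% and 84.4% over 18 bodies, from MS4A1 at 46.0% and 52.4% to CD14 at 86.2% and 91.8%, and ELANE had 58.2% and 75.5%. The percentiles in BS-seq were 0.725 for kidney, 0.06 for neuronal and adrenal, 0.03 for muscle and liver, and 8.72 for blood. With other matching or 2000 bp added, that of blood ranged from 3.57 to 25.4, and those of the other lists were at most 1.03. Of these lists' bodies, 0 kidney, 0 neuronal and adrenal, 1 muscle and liver and 2 blood genes differed, with the same counts adjusted over the list alone.

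Germline and cancer-testis genes had medians of 78.2% and 83.3% over 33 bodies, from PIWIL1 at 47.6% and 51.5% to DPPA5 at 86.3% and 92.2%, and MAGEA3 had the largest difference of -9.36 points. Pluripotency genes had 77.7% and 84.6% over 15 bodies, from DPPA4 at 66.2% and 75.1%, which also had the largest difference, to KLF4 at 86.2% and 90.1%. Housekeeping genes with CpG island promoters had 82.3% and 87.9% over 26 bodies, from EEF1A1, an elongation factor gene with the largest difference, at 41.2% and 51.0% to GUSB at 87.0% and 94.1%. No body of these 3 lists passed the size threshold with the adjusted test, over all genes or adjusted over the list alone.

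Gene ends of the remaining lists that differed were all lower in TAD-seq. Of those tested, 4 of 31 differed for housekeeping genes, 2 of 40 for germline genes, 4 of 16 for pluripotency genes and 4 of 24 for the DNA methylation machinery. The counts were 4 of 40 for kidney genes, 5 of 28 for neuronal and adrenal genes and 1 of 25 for blood genes, and each of these 7 counts was the same adjusted over the list alone. For muscle and liver genes 3 of 30 differed, and 4 adjusted over the list alone. Among the families, 17 of 163 olfactory receptor, 8 of 64 protocadherin, 29 of 222 zinc finger, 12 of 87 histone and 16 of 103 ribosomal protein gene ends differed, the last with 1 end counted under both RPL36A and RPL36A-HNRNPH2. Adjusted over the list alone, these counts were 16, 7, 27, 13 and 15. Among all tested gene ends 12.5% differed, and 2901 of those 2914 were lower in TAD-seq. The counts of the lists were not tested against that share.

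CpG-dense stretches were compared because a TET enzyme or a deaminase can depend on local sequence. The difference was -5.19 points where a cytosine had no other listed CpG site within 100 bp and -11.0 where it had over 20. The growth with density depended on the level. Where the partner strand was at least 80% methylated in BS-seq, the difference went from -5.52 to -6.63 points. Where the partner strand was between 40% and 80%, it went from -4.65 to -13.8, the last with a standard error of 1.18 over autosomes and 2271 cytosines.

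**Figure D3:**
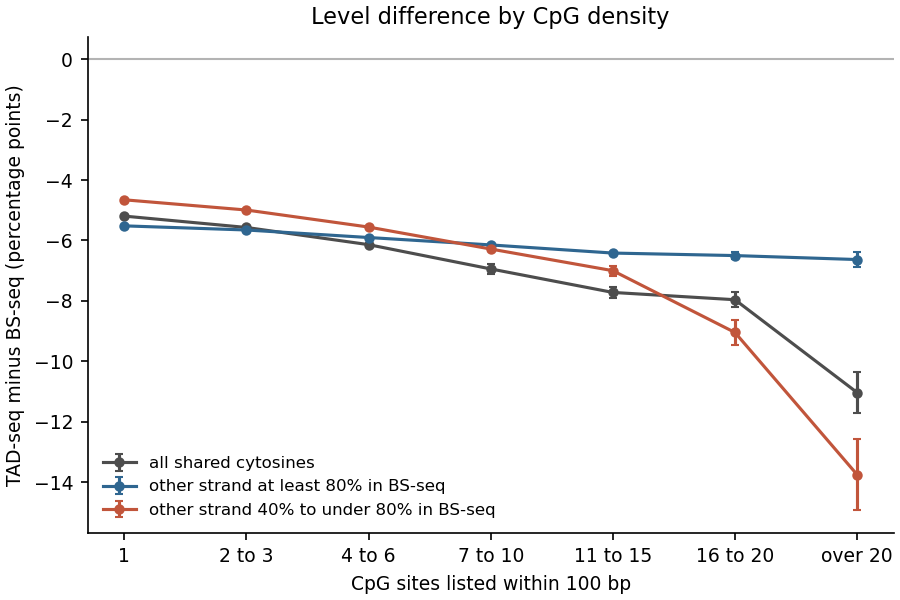
TAD-seq minus BS-seq level (percentage points) by the number of CpG sites listed within 100 bp, for all shared cytosines and for those chosen by the level of the partner strand in BS-seq, with standard errors over 22 autosomes. In the densest class the lines reach -11.0 for all cytosines, -6.63 for high partners and -13.8 for intermediate partners.

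Coverage was lower at higher CpG density in both libraries. Across 1 kb windows, Spearman's rho between mean reads per listed cytosine and listed CpG sites was -0.179 in TAD-seq and -0.295 in BS-seq. Windows with 100 or more sites had a median depth of 0.655 times that of all windows in TAD-seq and 0.715 times in BS-seq. Of cytosines at least 80% methylated on both strands in BS-seq, TAD-seq did not list 10.4% in the sparsest class and 62.7% (62.1 to 63.3) in the densest. In the other direction BS-seq did not list 7.35% and 38.3% (37.2 to 39.3) of those high in TAD-seq.

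**Figure D4:**
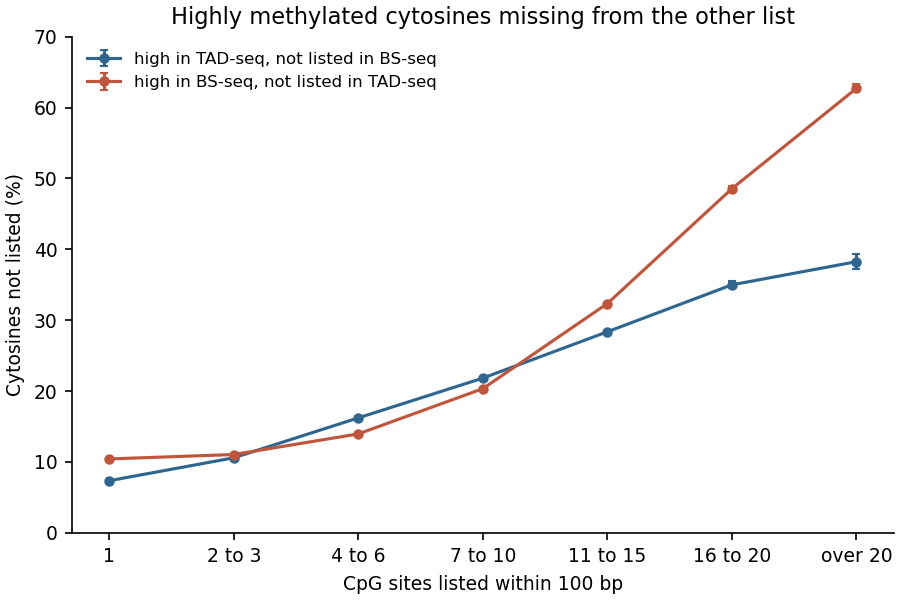
Share (%) of cytosines at least 80% methylated on both strands in one library that the other library did not list, by the number of CpG sites listed within 100 bp, with Wilson intervals. In the densest class TAD-seq did not list 62.7% of those high in BS-seq, and BS-seq did not list 38.3% of those high in TAD-seq.

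Outside CpG the lists differed mainly at CHH. TAD-seq listed 795182 CHH cytosines on the chromosomes and BS-seq 208371, which is 3.82 times as many in TAD-seq. Of the 649219 CHH cytosines listed by TAD-seq alone, 554917 had exactly 2 methylated reads, and their median level was 16.7%. With the stricter read minimum of the libraries applied to both, a setting added after seeing the data, the ratio was 1.17. CHG cytosines numbered 66525 in TAD-seq and 70770 in BS-seq, a ratio of 0.940, and with the same minimum 66525 and 62000, a ratio of 1.07 in the other direction. On the chromosomes the level was 62.2% in TAD-seq and 64.6% in BS-seq at listed CHG cytosines, and 25.1% and 61.0% at listed CHH cytosines. Both libraries listed 145963 CHH and 46603 CHG cytosines. At the shared CHH cytosines the mean level was 65.2% in TAD-seq and 70.7% in BS-seq and r was 0.727, and at the shared CHG cytosines 70.5% and 75.0% with r of 0.697. Mitochondrial DNA was not analysed here.

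**Figure D5:**
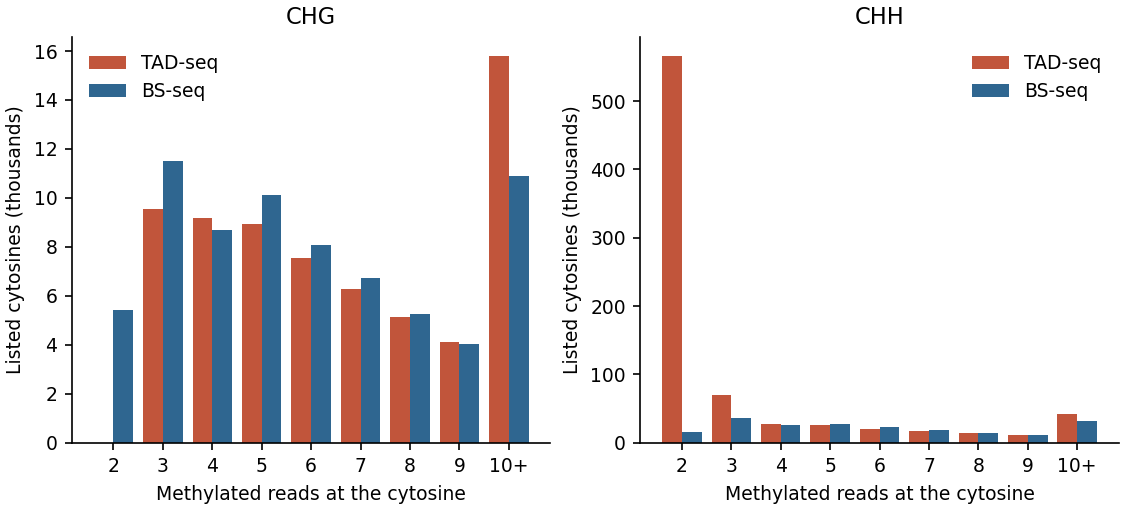
Number of listed CHG and CHH cytosines (in units of 1000) by the number of methylated reads at the cytosine in TAD-seq and BS-seq, with 10 or more reads in the last bar. TAD-seq has 565889 CHH cytosines with 2 methylated reads, and none in CHG.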

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

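The tests of error rates, of cytosines in both lists, of the ratio of levels, of partner strands without unmethylated reads, and of the growth of the deficit at highly methylated cytosines were chosen only after the result was seen. Signal lay outside the chromosomes that the comparisons used: TAD-seq listed 46321 CpG cytosines on unplaced scaffolds, with a level of 34.1%, and BS-seq listed 43755, with a level of 43.7%.

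TAD-seq read a lower level at CpG cytosines on every chromosome compared. The error rates behind the deposited p-values differed by only 0.123 percentage points. They are fixed inputs of unstated origin and need not measure conversion at genomic CpG cytosines, so unconverted cytosines in BS-seq stay open. The difference of -5.84 over cytosines in both lists argues against low-level cytosines listed by TAD-seq alone. Lost unmethylated molecules in BS-seq would leave little difference where nearly every molecule is methylated. The difference was -5.74 where the partner strand had no unmethylated read. Levels there were only 87.7% in TAD-seq and 93.4% in BS-seq, so that value cannot decide. A loss at 1 rate would also give a larger difference at intermediate than at high partner levels. Over all densities these were -5.14 and -5.78, which argues against such a loss, but in the densest class they were -13.8 and -6.63. A nearly fixed share of 5-methylcytosine read as T in TAD-seq is a candidate explanation for the difference over all densities. The ratio of levels was 0.936 at high and 0.924 at intermediate partner levels. An exactly fixed share would not give that gap of 0.0122. With over 20 CpG sites within 100 bp the ratios were 0.929 and 0.785, and with 16 to 20 sites 0.930 and 0.868. A nearly fixed share would not by itself give these values in CpG-dense stretches. Differences between cultures or DNA preparations stay open and untested, and no biological explanation was tested.

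In CpG-dense stretches the deficit of TAD-seq was larger. 5-methylcytosine read as T more often at high density stays open. At highly methylated cytosines in both lists the deficit grew by -1.12 points, against -9.10 at intermediate ones, but TAD-seq did not list 62.7% of the densest and 10.4% of the sparsest cytosines high in BS-seq, and those most affected would be among them. Greater depth in TAD-seq acting through the listing rule is argued against as the only cause by cytosines where TAD-seq had no more reads. Among intermediate ones, the difference there was -9.66 in the densest class, over 1087 cytosines, and -3.75 in the sparsest. That growth of -5.91 points was smaller than the -9.10 at all intermediate cytosines, so a part played by depth stays open. Fewer reads from methylated CpG-dense molecules in TAD-seq stay open too: the ratio of methylated reads between the libraries in the densest class was 0.844 times that in the sparsest, against 1.22 times for unmethylated reads, but any growing deficit splits them this way. No biological explanation was tested, since both libraries come from the same cell line.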

How the results depend on the processing

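Chosen only after the result was seen were the settings of cytosines in both lists, at least 2 methylated reads, the stricter read minimum, BS-seq methylated reads thinned by the overall ratio, the median gene or gene end, gene length, and, for dense stretches, high partners and the deepest sites. The CpG level difference of -6.48 kept its sign in all 6 settings run. It was -5.20 as a mean of site levels at 10 reads, -5.67 with 10 reads in both, -6.47 on autosomes, -6.44 without the deepest 0.1% of sites, -5.84 at cytosines in both lists and -6.31 with at least 2 methylated reads. At CHG, -2.34 became -5.14 with 10 reads in both and -5.50 at cytosines in both lists. At CHH, -35.9 became -5.47 and -5.63 in the same settings, and stayed at -35.9 on autosomes. The ratio of CHH counts went from 3.82 to 1.17 with the stricter read minimum, which left 242801 of 795182 in TAD-seq and all 208371 in BS-seq, and that of CHG from 0.940 to 1.07. Site r was 0.769 at 5 reads, 0.865 at 20 and 0.803 per strand, and bin r was 0.976 at 10 kb, 0.999 at 1 Mb and 0.994 at 20 reads. The 17 sites that differed became 26 at 20 reads, where fewer sites were tested, 149 with no size threshold, 0 without the deepest 0.1%, where 6 of the 17 were still tested, 8 with TAD-seq thinned to the BS-seq total and 1 with BS-seq methylated reads thinned. The 2914 gene ends became 365 in windows of 200 bp, where fewer ends were tested, 30 at 25 points and 557 from the median gene end. The 481 gene bodies became 66 from the median gene. Both settings from the median kept the adjusted test against equal levels. The excess inside genes, 0.0176 points larger in TAD-seq, reversed to -0.332 as a mean of site levels at 10 reads. The extra deficit with at least 16 CpG sites within 100 bp over that with 1 site, -3.38, was -5.83 with 10 reads in both, -1.01 with high partners and -3.19 without the deepest 0.1%. Where no reason is given, the cause was not tested. Of 17 lists, 10 had a BS-seq median outside the central 95% of matched lists, and 10 with 2000 bp added, 9 matched also on reads and 10 matched on gene length, but not the same lists. The Polycomb-marked factors, at percentile 1.78, left in each of these settings, at 14.6, 2.62 and 22.2. Histone genes, at 71.6, moved to 0 with 2000 bp added and to 98.1 matched on gene length, which are opposite tails. For differences the count was 6, and 8, 4 and 5 in the same settings, again with changed lists. Protocadherins and zinc finger genes were outside in all of them on the more negative side. Olfactory receptors were outside in all of them on the less negative side. Ribosomal protein genes were outside only without these settings, also on the less negative side. Sites outside CpG islands were not run, and a minimum of 5 reads changes no bin, since every listed cytosine has 5. No paired analysis was possible because each method had 1 library.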

Other observations

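The test of neighbouring CpG levels was written before its result was seen, and the test of shifted lists after. Of the CHH cytosines in both lists, 37.9% were at least 80% methylated in TAD-seq and 46.1% in BS-seq. Their mean levels of 65.2% and 70.7% lay below the 74.1% and 80.1% of listed CpG cytosines. Chance overlap of conversion failures is argued against, since the lists shared 1877 times as many CHH cytosines as lists shifted by 1 and 5 kb. Whether they are CpG sites of the cell line that the reference lacks stays open. Shared CHH levels followed the CpG level within 200 bp with r of 0.277, against 0.103 for CHH cytosines listed by TAD-seq alone, whose levels have a narrow range since most have 2 methylated reads. At CHG, where no listed TAD-seq cytosine has so few, r was 0.263 for both kinds. Methylation of true non-CpG cytosines stays open as well.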
